A study of Caenorhabditis elegans with 12 samples.

How the data were processed

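H4K5ac and H4K8ac were each measured by chromatin immunoprecipitation and sequencing in whole adult N2 worms, with 3 precipitated (IP) and 3 input libraries per mark. Per the labels' protocols, worms were grown at 20 °C and chromatin was sheared to fragments of 0.2 to 1 kb. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0, and the builds WBcel235 and hg38, without saying which step used which. Of the table lines matched to a gene, 99.98% lay on that gene's chromosome in WBcel235 for both marks, so coordinates are given in that build, as the files list them. The replicates are numbered by the labels, which do not say whether they came from separate cultures; p-values therefore measure only the spread between these samples, which may be technical. No genome sequence was used here.

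The authors deposited, for each mark, 1 list of peak regions with the same lines in all 6 libraries, and 1 estimated count per gene and library that is not normalized and is repeated on each region of the gene. Whether regions were called per sample or on pooled samples, and which tool counted the reads, is not given in the sources used here. Deposited counts did not follow the length of the region (Spearman correlation of length with mean input count 0.0106 for H4K5ac and -0.0037 for H4K8ac, across regions). They fell with the number of annotated genes whose span meets the window around the gene's transcription start site (TSS) (-0.504 and -0.50, across genes). A window reaches 2 kb to either side of the TSS. Many counts were fractions. The counts thus behave like reads in such a window, divided between genes whose windows overlap, and a gene with close neighbours is uncertain. Regions are listed by decreasing IP over input (Spearman -1.0 for both marks), and the lists stop at a lowest log2 ratio of -0.17 for H4K5ac and -0.31 for H4K8ac as deposited, with 2868 and 2881 of the region numbers missing. The tables therefore hold genes chosen for enrichment, and folds are relative to the typical listed gene, not to the genome.

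Gene names were taken from the files and from a RefSeq gene table of assembly WBcel235. Of 5632 genes listed for H4K5ac, 5614 matched that table, and of 5671 for H4K8ac, 5648 did; 7 and 6 names that a spreadsheet had turned into dates were read from their transcript. The tables had 3750 genes in common, with 1882 and 1921 genes in 1 table only. A fit of all 12 samples was therefore possible for the 3750 common genes alone, which departs from the plan. A fit of each table by itself was added after seeing the data.

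Estimated counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, 1 mean per group over all 12 samples, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The filter on low counts removed 0 genes, and the common dispersion was 0.00379. Comparisons were each IP against its input, the difference of those folds, the IPs directly, and the inputs as a negative control. Standard errors of log2 folds come from that fit. Levels are in CPM, counts scaled by library size, with the SD over 3 libraries. Total counts ranged from 5460429 to 9156392. Replicates differed beyond counting noise in all 12 pairs within groups (chi-square per degree of freedom 1.31 to 24.0), so none was treated as a duplicate. The steps were tested on simulated data with 200 changed genes of 3750, where 83.6% of log2 changes of 0.32 and 100% of 0.58 were recovered for H4K5ac IP against input. These shares were 32.8% and 98.5% for the difference between marks, and 79.1% and 100% for the IPs compared directly. Simulated IPs and inputs shared 1 dispersion per gene, so these shares may be too high where real IPs vary more.

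Gene lists fixed before the data were examined covered fatty acid and triglyceride synthesis, lipolysis and beta-oxidation, lipid storage and transport, histone deacetylases and sirtuins, deacetylase complex subunits, histone acetyltransferases and bromodomain proteins, insulin-like signalling and stress, germline and oocyte, neuron, muscle, intestine, mitochondrially encoded genes (0 measured), ribosomal proteins, proteasome, core histones, collagens, sperm, chemoreceptors, F-box, MATH and BATH proteins, C-type lectins, nuclear hormone receptors, transfer RNA and piRNA genes. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, adjusted by Benjamini-Hochberg over the 21 lists. The transfer RNA list was taken by gene name. Its 49 members in both tables exceeded the 41 genes annotated there as tRNA, so it may hold tRNA pseudogenes (19 in the H4K5ac table). X-linked genes were tested against autosomal ones in the same way as lists, unadjusted.

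Regions of the marks were compared by an overlap of 1 bp, against 1000 shifts along each chromosome. List genes overlapped by a region were compared with 10000 random protein-coding lists matched in 20 classes of gene length, in a permutation test with two-sided p-values adjusted by Benjamini-Hochberg. That use of region coordinates was added after seeing the data.

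The rule for named genes was also set before the data were examined. It took the 6 highest and 6 lowest log2 folds per mark among genes past the threshold with the same sign in all 3 same-numbered differences of IP and input. It further took 3 each way for the difference between marks by the same rule or, as none passed, the 3 with the lowest p. Also named were all deacetylases and sirtuins and, in every other list, the 2 measured members with the lowest p for each mark. Genes named for their regions alone were chosen after their overlaps were seen.

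Same-numbered IP and input libraries of H4K5ac deviated together from their group means across genes (correlations 0.286, 0.114 and 0.233), so by the rule of every pair over 0.1 their numbers pair the samples, a hint from the data and not from the labels. The H4K8ac pairs gave -0.259, -0.152 and 0.073 and are not paired. Alternatives fixed beforehand were the replicate number as a block, over all groups or within a mark; DESeq2 1.42.0; its size factors in edgeR; total count scaling; no filter; an adjusted p of 0.01; only the groups compared; each library left out; and, for the chromosomes, genes above the median level. Added after seeing the data were equal IP strength (offsets giving each IP the same slope on the mean enrichment), scaling to the least enriched 10% of genes, genes with no other gene within 2 kb, each mark's own table, and leaving out the strongest and the weakest IP. Tables and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.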

Results

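Acetylation of lysines 5 and 8 of histone H4 was profiled by chromatin immunoprecipitation and sequencing in whole adult worms of the Bristol N2 strain, the standard wild-type laboratory strain of Caenorhabditis elegans, grown on Escherichia coli OP50 at 20 °C. The 12 samples fell into 4 groups of 3 replicates: chromatin precipitated with an antibody against H4K5ac, chromatin precipitated with an antibody against H4K8ac, and the input DNA of each mark. The series title asks how genes of histone deacetylation act on lipid metabolism through these 2 residues. Every sample was wild type, so the comparisons describe where the marks lie and not the effect of any mutation. The deposited values were 1 estimated read count per gene for genes annotated to a peak region. Total counts were 9156392, 8291315 and 8210104 for the H4K5ac immunoprecipitates (IP) and 6206517, 8911486 and 5460429 for their inputs. They were 9136344, 7599959 and 7842391 for the H4K8ac IPs and 8277792, 8378727 and 6418842 for their inputs. Each fold below compares a gene with the typical gene of the 3750 listed for both marks, so "lower" means less enriched than that gene and not depleted of the mark.

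Regions of the marks overlapped each other more than regions shifted along the chromosomes. The H4K5ac list held 6432 regions over 36.0 Mb and the H4K8ac list 6397 regions over 39.9 Mb in WBcel235 coordinates. Of the H4K5ac regions, 5644 overlapped a H4K8ac region by at least 1 bp. In the other direction 5310 of the H4K8ac regions overlapped a H4K5ac region. The share of the combined length that carried both marks was 0.741, against a mean of 0.266 and a highest value of 0.306 when the regions were shifted along their chromosomes 1000 times. H4K5ac regions covered 54.4% of chromosome III and 51.1% of chromosome I, but 23.6% of chromosome V and 23.1% of X. H4K8ac regions covered 58.0%, 56.0%, 28.3% and 21.5% of the same chromosomes. Of the protein-coding genes, 38.7% of the X-linked and 55.6% of the autosomal ones were overlapped by a H4K5ac region, and 36.5% and 61.5% by a H4K8ac region.

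Genes of protein synthesis and breakdown, core histone genes and germline genes mostly lay under listed regions of the marks, and large families of receptors and adaptors mostly did not. Region numbers are missing from both lists, which end at different ratios of IP over input. A gene outside the listed regions is therefore not shown to lack the mark. H4K5ac regions overlapped 77 of 78 ribosomal protein genes, all 33 proteasome genes, 66 of 72 core histone genes and 29 of 30 germline and oocyte genes. H4K8ac regions overlapped 77, 33, 65 and 28 of them. Only 91 of 1301 chemoreceptor genes (7.0%) lay under a H4K5ac region and 140 (10.8%) under a H4K8ac region, where random protein-coding genes of like length gave means of 47.7% and 53.3%. F-box, MATH and BATH genes (103 and 131 of 394), nuclear hormone receptor genes (103 and 126 of 269) and C-type lectin genes (77 and 111 of 239) were also overlapped less often than random genes, by the 2 marks in that order. The permutation test against 10000 random lists gave an adjusted p of 0.000444 for H4K5ac in all of these groups, the smallest the lists can give. For H4K8ac it was 0.0128 for the lectins and 0.0005 for the rest. Collagen genes (106 and 114 of 156; adjusted permutation p = 0.000444 and 0.0005) and muscle genes (19 and 18 of 20; 0.00433 and 0.0447) were overlapped more often than random genes. Sperm genes were overlapped more often by H4K8ac (57 of 81; adjusted permutation p = 0.00133) and not detectably by H4K5ac (39; 0.788). Random lists ignore that the members of a family lie side by side, so the p-values of clustered families are too small.

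**Figure D1:**
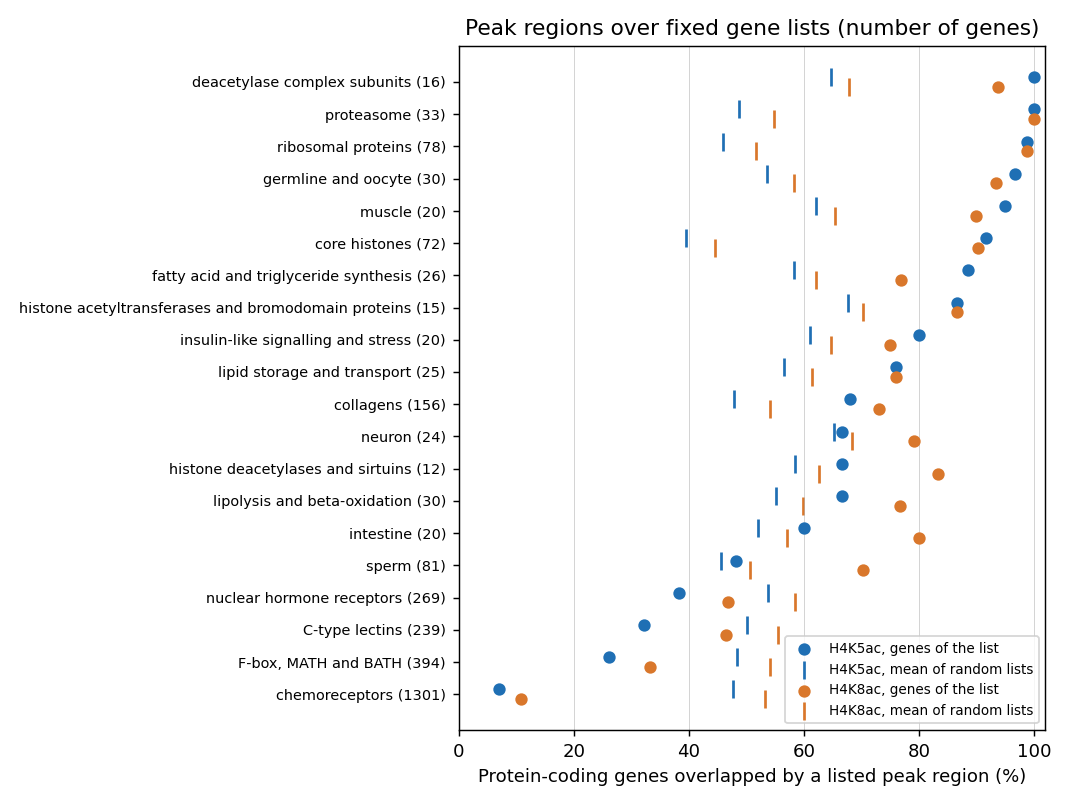
Share of the protein-coding genes of each list, fixed before the data were examined, that a listed peak region overlaps (%, horizontal axis), for H4K5ac in blue and H4K8ac in orange; vertical ticks are means of 10000 random lists of like gene length. Ribosomal, proteasome and germline genes lie to the right of their ticks, and chemoreceptors, at 7.0% and 10.8%, far to the left.

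Genes of fat synthesis were overlapped by H4K5ac regions, by at least 1 bp, more often than random genes. H4K5ac regions overlapped 23 of the 26 genes of fatty acid and triglyceride synthesis (88.5%, random mean 58.4%; adjusted permutation p = 0.0032), among them the elongase genes elo-1, elo-2, elo-5 and elo-6 and the desaturase genes fat-1 to fat-6. H4K8ac regions overlapped 20 of them (76.9%, random mean 62.2%; adjusted permutation p = 0.217), and missed pod-2, which encodes acetyl-CoA carboxylase, pmt-2 and acl-1. The difference between the marks was not tested. Regions covered at least 0.5 of the gene's length in 19 of the 26 genes for H4K5ac and 18 for H4K8ac. That stricter measure was not compared with random lists, which were matched on gene length alone. The desaturase gene fat-7 and the genes pmt-1 and cept-1 of phospholipid synthesis lay under no listed region of either mark. As the lists lack region numbers, neither this nor a gene missed by 1 mark shows that a mark is absent. Lipolysis and beta-oxidation genes (20 and 23 of 30; adjusted permutation p = 0.343 and 0.118) and lipid storage and transport genes (19 and 19 of 25; 0.102 and 0.234) did not differ detectably from random genes. The vitellogenin gene vit-4 and the fatty acid binding protein genes lbp-7 and lbp-8 lay under no listed region of either mark. Among the histone deacetylase and sirtuin genes, 8 of 12 were overlapped by H4K5ac and 10 by H4K8ac (adjusted permutation p = 0.817 and 0.256), and hda-4 and sir-2.4 by neither. Genes of deacetylase complex subunits were overlapped by H4K5ac in all 16 cases and by H4K8ac in 15 (adjusted permutation p = 0.00364 and 0.0563). Genes of histone acetyltransferases and bromodomain proteins (13 and 13 of 15; adjusted permutation p = 0.243 and 0.294), insulin-like signalling and stress (16 and 15 of 20; 0.166 and 0.466), neurons (16 and 19 of 24; 1 and 0.366) and the intestine (12 and 16 of 20; 0.738 and 0.0809) did not differ detectably from random genes. Non-coding genes had no matched random lists. Of 807 genes on the transfer RNA list, pseudogenes possibly included, 390 and 386 were overlapped, and of 15363 piRNA genes 448 and 519.

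Among the 3750 genes listed for both marks, the highest H4K5ac fold over input was at R107.5 (log2 fold change 1.88 ± 0.14, SE, n = 3 per group, edgeR adjusted p = 2.25e-08). It had 1051 ± 225 CPM (counts scaled by library size) in the IPs and 285 ± 15.7 in the inputs (SD). Its region, at chromosome III 9043401 to 9065199, covers a promoter, and its inferred counting window also holds cls-2, a gene for a microtubule-binding protein. Next came hsp-1, the gene of a heat shock cognate chaperone (1.62 ± 0.13, edgeR adjusted p = 2.97e-08; chromosome IV 17265801 to 17291999, promoter), and abcf-2, the gene of an ATPase of the ABC family (1.60 ± 0.12, edgeR adjusted p = 2.25e-08; chromosome III 13455801 to 13467399, at a transcription end). The short non-coding genes M04B2.10 (1.57) and F16A11.9 (1.54) and the gene W03F9.1 (1.51) followed. Because the counts behave as if reads were divided between genes whose windows overlap, the gene behind such a signal is uncertain. M04B2.10 shares its inferred window with gfl-1 and the chromatin gene mep-1, and W03F9.1 with sftb-2. The lowest folds lay between -0.41 and -0.42 and belonged to Y16B4A.2, the synaptotagmin gene snt-3, C34H3.5, the ferritin gene ftn-1, linc-157 and T09B4.13. Of the 3750 genes, 2552 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1267 higher and 1285 lower, with log2 folds from -0.42 to 1.88. Scaling by total count moved the median of all genes to -0.13 and the split to 957 higher and 1770 lower (35.1% higher against 49.7%). Scaling to the least enriched genes, added after seeing the data, moved that median to 0.34 and gave 2669 calls, all higher. The direction of a call therefore holds only relative to the typical listed gene.

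Among the lists fixed beforehand, ribosomal protein genes stood highest for H4K5ac. All 6 of those measured were higher (median log2 fold 0.82; camera adjusted p = 2.71e-05), among them rla-0 (1.21 ± 0.10) and rpl-19 (0.78 ± 0.08). Of 22 C-type lectin genes, 19 were lower and 1 higher (median -0.32; camera adjusted p = 0.0011). Among the lower ones clec-72 had the lowest p (-0.41 ± 0.07), and clec-87, which lies beside the tRNA synthetase gene iars-2, was the higher one (0.50 ± 0.08). Of 50 nuclear hormone receptor genes, 27 were lower and 6 higher (median -0.17; camera adjusted p = 0.00445), from nhr-90 (-0.41 ± 0.06) to nhr-61 (0.54 ± 0.09), which shares its window with the ribosomal protein gene rpl-37.1. Of 43 F-box, MATH and BATH genes, 27 were lower and 5 higher (median -0.22; camera adjusted p = 0.00485), with fbxc-52 at -0.39 ± 0.06 and bath-40 at 0.99 ± 0.09. None of these 4 lists passed when the correlation between members was estimated: the adjusted p with an estimated correlation was 0.385 for ribosomal, 0.486 for lectin, 0.363 for receptor and 0.385 for F-box genes. Adjusted over the list alone, the lectin count was 20 lower and 1 higher and the other 3 counts stayed as given. The count of lists past the preset test was 7 without H4K5ac IP replicate 1, without H4K5ac input replicate 2 or without H4K5ac input replicate 3.

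Lipid genes went both ways for H4K5ac and no lipid list passed the set test. Of 9 measured genes of fatty acid and triglyceride synthesis, 4 were higher and 3 lower (median 0.12, camera adjusted p = 0.997). All 14 members in the H4K5ac table, a fit added after seeing the data, gave 4 higher and 7 lower (median -0.17, camera adjusted p = 0.437). The elongase gene elo-1 was at 0.36 ± 0.07 (edgeR adjusted p = 0.000141; promoter region at chromosome IV 9522201 to 9531599). The fatty acid synthase gene fasn-1 was at -0.32 ± 0.08 (edgeR adjusted p = 0.00127; exon region at chromosome I 8974601 to 8987799). Of 9 genes of lipolysis and beta-oxidation, 4 were higher and 3 lower (median 0.11, camera adjusted p = 0.818). The carnitine palmitoyltransferase gene cpt-2 was at 0.72 ± 0.06 (edgeR adjusted p = 6.95e-08; promoter region at chromosome IV 11177401 to 11187199) and the nuclear receptor gene nhr-13 at -0.30 ± 0.06 (edgeR adjusted p = 0.000296; exon region at chromosome V 2192001 to 2194999). Of 10 genes of lipid storage and transport, 2 were higher and 4 lower (median -0.10, camera adjusted p = 0.707). The higher ones were the lipid binding protein gene lbp-9 (1.23 ± 0.13, edgeR adjusted p = 4.53e-07), which shares its window with nhr-86, and the perilipin gene plin-1 (0.56 ± 0.09, edgeR adjusted p = 3.07e-05). The counts of these 3 lists were the same adjusted over the list alone.

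Genes of the acetylation machinery were mostly higher for H4K5ac without passing the set test. Of 8 deacetylase complex genes, 5 were higher and none lower (6 higher adjusted over the list alone; median 0.31, camera adjusted p = 0.0534), led by rba-1 (0.74 ± 0.06), which lies beside its paralog lin-53, and let-418 (0.47 ± 0.07), the gene of a Mi-2 chromatin remodeller. Of 7 acetyltransferase and bromodomain genes, 4 were higher and 1 lower (median 0.54, camera adjusted p = 0.0877), with the histone acetyltransferase gene hat-1 at 0.71 ± 0.08 and the bromodomain gene bet-1 at 0.63 ± 0.09. Of the deacetylases and sirtuins only sir-2.2 was measured (-0.14 ± 0.07, edgeR adjusted p = 0.0648), since the other genes of that list were not the gene named for a region in both tables. The energy sensor gene aak-2 was higher (0.55 ± 0.10) and the insulin receptor gene daf-2 lower (-0.24 ± 0.06), with 5 of the 7 measured insulin and stress genes not passing (camera adjusted p = 0.997). The remaining lists are given by members higher and lower. They were germline and oocyte (3 and 1 of 8, with pgl-3 at 0.48 and puf-6 at 0.41), neuron (0 and 2 of 6, cha-1 -0.19 and sbt-1 -0.20) and muscle (2 and 5 of 9, act-4 0.59 and mlc-3 0.39). Next were intestine (0 and 3 of 7, ftn-1 -0.42 and lys-1 -0.29), proteasome (3 and 0 of 4, rpt-6 1.27 and rpn-11 0.50) and core histones (0 and 4 of 5, his-38 -0.32 and his-32 -0.27). Collagens (6 and 17 of 41), sperm genes (2 and 6 of 9), chemoreceptors (2 and 12 of 14), transfer RNA genes (8 and 23 of 49) and piRNA genes (13 and 25 of 57) completed them. The camera adjusted p of these 11 lists ranged from 0.0634 to 0.818, and only the collagen count changed adjusted over the list alone (6 and 16). In the H4K5ac table, a fit added after seeing the data, core histones had 2 higher and 3 lower of 10 (median -0.029, against -0.24 here).

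**Figure D2:**
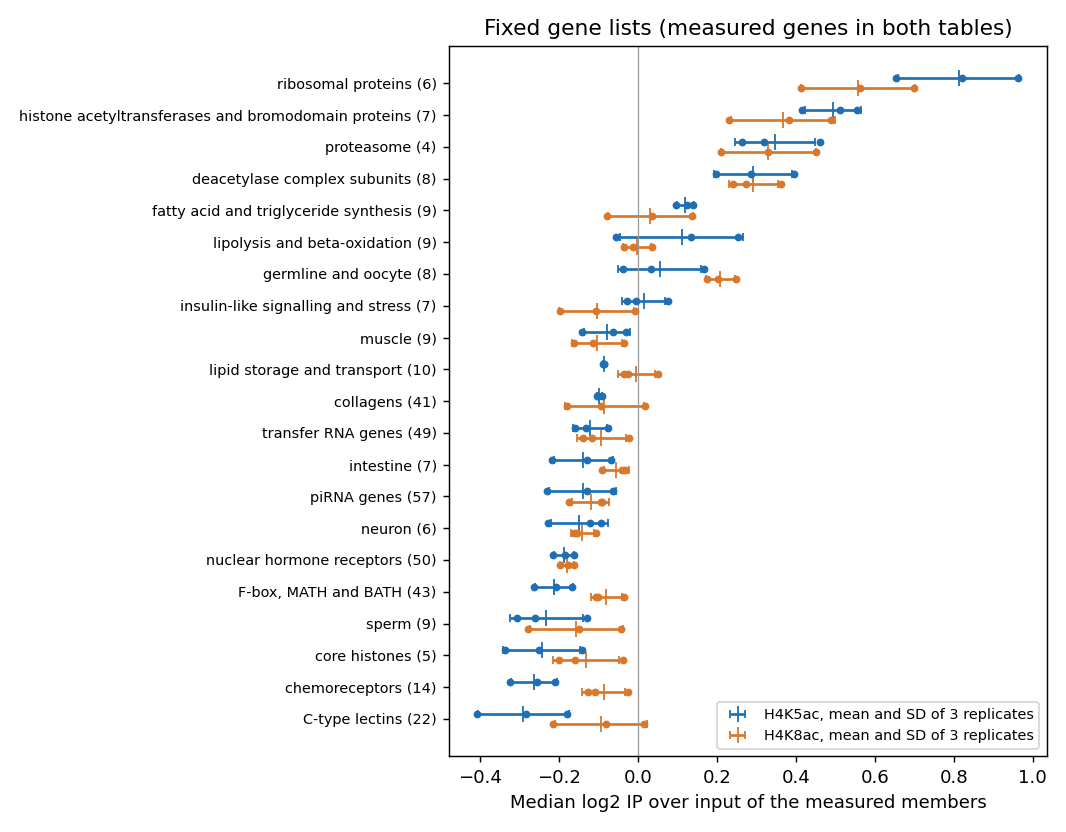
Median log2 IP over input of the measured members of each list (horizontal axis; number of members in brackets), with H4K5ac in blue and H4K8ac in orange; points are the 3 replicates, ticks and bars their mean and SD. Values are relative to the typical gene of both tables, with ribosomal protein genes highest and C-type lectin genes lowest for H4K5ac.

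H4K8ac was highest at many of the genes that led for H4K5ac. R107.5 again had the highest fold (1.47 ± 0.14, SE, n = 3 per group; edgeR adjusted p = 1.08e-06; 830.3 ± 107.9 CPM in the IPs and 299 ± 3.65 in the inputs). It was followed by hsp-1 (1.23 ± 0.13), M04B2.10 (1.18 ± 0.12), W03F9.1 (1.16 ± 0.10), F22D6.2, now named mstr-1 (1.14 ± 0.12), and abcf-2 (1.14 ± 0.12). The lowest folds, from -0.36 to -0.37, belonged to the transfer RNA gene R04E5.t6, C50B8.6, Y105C5B.19, the DNA repair gene xpc-1, the collagen gene col-184 (chromosome X 13469601 to 13470399, exon) and C09H10.17. In edgeR's quasi-likelihood test 2051 of 3750 genes passed, 1152 higher and 899 lower. Total count scaling gave 901 higher and 1393 lower (39.3% higher against 56.2%). Scaling to the least enriched genes gave 2597 calls, all higher, around a median of 0.28.

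Nuclear hormone receptor genes were lower and ribosomal protein genes higher for H4K8ac, as the 2 lists past the set test. Of 50 receptor genes 24 were lower and 3 higher (22 and 3 adjusted over the list alone; median -0.16, camera adjusted p = 0.000191, adjusted p = 0.112 with an estimated correlation), with nhr-183 at -0.35 ± 0.06 and nhr-61 at 0.53 ± 0.09. All 6 ribosomal protein genes were higher, also adjusted over the list alone (median 0.56, camera adjusted p = 0.000729, adjusted p = 0.551 with an estimated correlation), with rpl-11.1 at 0.87 ± 0.12 and rla-0 at 0.84 ± 0.10. Fatty acid and triglyceride synthesis (3 higher and 3 lower of 9; camera adjusted p = 0.895), lipolysis and beta-oxidation (3 and 3 of 9; 0.895) and lipid storage and transport (3 and 3 of 10; 0.895) went both ways, with the same counts adjusted over the list alone. The higher lipid genes included the desaturase gene fat-4 (0.41 ± 0.09, edgeR adjusted p = 0.000646; promoter region at chromosome IV 9792001 to 9806599), elo-1 (0.32 ± 0.06), cpt-2 (0.62 ± 0.06), lbp-9 (0.92 ± 0.13) and plin-1 (0.57 ± 0.09). The lower ones included nhr-13 (-0.32 ± 0.06) and fasn-1 (-0.23 ± 0.08, edgeR adjusted p = 0.016). The sirtuin gene sir-2.2 was lower (-0.32 ± 0.07, edgeR adjusted p = 0.00062).

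Deacetylase complex genes were higher for H4K8ac in 6 of 8 cases and lower in none (camera adjusted p = 0.101; rba-1 0.60, let-418 0.43). Acetyltransferase and bromodomain genes were higher in 4 of 7 cases with 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.167; trr-1 0.59, pbrm-1 0.44). Germline and oocyte genes were higher in 5 of 8 cases (6 adjusted over the list alone; camera adjusted p = 0.167; pgl-3 0.54, glh-2 0.44). The catalase gene ctl-2 was higher (0.33 ± 0.08, edgeR adjusted p = 0.00305) and daf-2 lower (-0.25 ± 0.06, edgeR adjusted p = 0.00296) among 2 higher and 3 lower of 7 insulin and stress genes (camera adjusted p = 0.521). By members higher and lower, the other lists were neuron (0 and 2 of 6, sbt-1 -0.29 and mec-7 -0.19), muscle (2 and 4 of 9, tnt-2 -0.31 and the paramyosin gene unc-15 -0.31), and intestine (0 and 2 of 7, ftn-1 -0.22 and lys-1 -0.17). Next were proteasome (3 and 0 of 4, rpt-6 0.75 and rpn-11 0.42), core histones (0 and 1 of 5, his-38 -0.21), collagens (7 and 12 of 41, col-120 0.45) and sperm (1 and 5 of 9, spe-15 0.45 and spe-48 -0.35). Chemoreceptors (2 and 5 of 14, sri-5 0.39), F-box, MATH and BATH (8 and 14 of 43, fbxa-216 0.34), C-type lectins (1 and 5 of 22, clec-258 -0.26), transfer RNA (9 and 18 of 49, Y49E10.t1 0.49) and piRNA genes (9 and 20 of 57, 21ur-15312 0.51) completed them, and the camera adjusted p of these 12 lists ranged from 0.149 to 0.297. Adjusted over the list alone, the lectins had 1 higher and 1 lower, the collagens 6 and 11, the chemoreceptors 2 and 4 and the intestine 0 and 1.

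Whether the marks lie on the same genes was asked next, and most genes called for H4K8ac were called in the same direction for H4K5ac. Of the 3750 genes, 1007 were called higher for both marks and 727 lower for both, where independent lists of these sizes would share 389 and 308. Total count scaling gave 783 and 1232, and scaling to the least enriched genes, added after seeing the data, 2329 and 0. Another 9 genes were called in opposite directions. Across genes, which are not independent replicates, the folds of the marks had a Pearson correlation of 0.92 and a covariance of 0.0976. The H4K5ac fold increased by 1.18 per unit of H4K8ac fold. This slope was 0.92 with equal IP strength and 0.95 without the strongest and the weakest IP, both added after seeing the data. The marks had separate input libraries, so no control was shared between the fits.

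**Figure D3:**
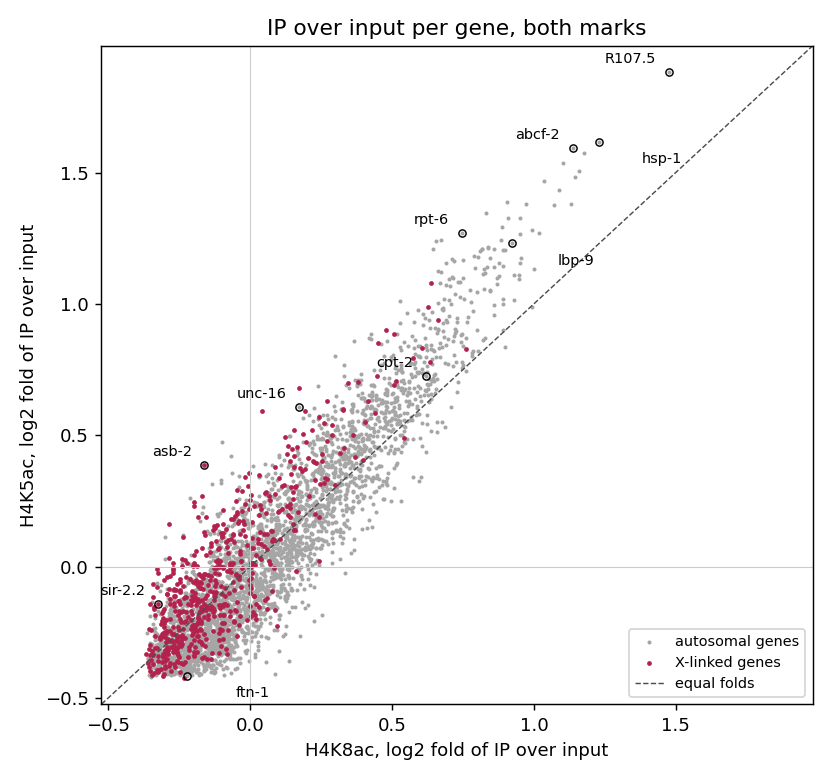
Log2 fold of IP over input per gene for H4K8ac (horizontal axis) and H4K5ac (vertical axis), each point 1 of 3750 genes, X-linked genes in red, with a dashed line of equal folds. Highly enriched genes such as R107.5 (1.47 and 1.88) lie above the line, and the least enriched genes end at a floor near -0.4.

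No single gene differed detectably between the marks once each was compared with its input. The gene unc-16, whose product is a scaffold of axonal transport, had folds of 0.61 for H4K5ac and 0.17 for H4K8ac (difference 0.43, adjusted p = 0.144). The mitochondrial ATP synthase gene asb-2 had folds of 0.39 and -0.16 (difference 0.55, adjusted p = 0.144), and the non-coding gene T14G11.6, which shares its window with immt-1, had 0.23 and -0.20 (difference 0.43, adjusted p = 0.144). These had the lowest p and did not pass. edgeR's quasi-likelihood test called 0 of 3750 genes, with 549 at an unadjusted p under 0.05, and DESeq2 called 41. In simulated data the same test recovered 32.8% of differences of 0.32 on the log2 scale and 98.5% of differences of 0.58, so many differences of the smaller size would be missed. The simulated libraries shared 1 dispersion per gene, while real replicate IPs mostly varied more than inputs. The highest real difference, 0.58, was not called, so larger differences may be missed more often than simulated. The count was 193 without H4K5ac IP replicate 3 and 7 without H4K5ac IP replicate 1.

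Some gene groups did differ between the marks by the preset set test. Ribosomal protein genes were more enriched for H4K5ac (median difference 0.30; camera adjusted p = 0.00141), with 4 of 6 members higher adjusted over the list alone and 0 over all genes. C-type lectin genes were less enriched for H4K5ac (median difference -0.20, negative in all 22 genes; camera adjusted p = 6.36e-07), as were F-box, MATH and BATH genes (-0.11; 0.000123) and chemoreceptor genes (-0.13; 0.0168). None of the 4 passed with an estimated correlation: the adjusted p with an estimated correlation was 0.449 for the ribosomal and lectin genes and 0.279 for the F-box and chemoreceptor genes. With equal IP strength, added after seeing the data, the ribosomal (camera adjusted p = 0.174) and chemoreceptor genes (camera adjusted p = 0.112) did not pass and the lectin and F-box genes did. Adjusted over the list alone, 1 lectin and 1 chemoreceptor gene were lower, and 1 lipolysis gene and 1 muscle gene were higher and 1 lipid storage gene lower; over all genes none was.

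The direct comparison of the H4K5ac and H4K8ac IPs, without inputs, gave more calls. Among named genes, asb-2 (0.53 ± 0.08, SE, n = 3 per group; edgeR adjusted p = 0.00686), rpt-6 (0.52 ± 0.13, edgeR adjusted p = 0.0222), the ribosomal protein gene rla-0 (0.40 ± 0.09, edgeR adjusted p = 0.0159), act-4 (0.39 ± 0.08, edgeR adjusted p = 0.00949) and hat-1 (0.29 ± 0.08, edgeR adjusted p = 0.0291) were higher in the H4K5ac IPs. All 6 ribosomal genes were higher adjusted over the list alone and 3 over all genes, and 6 lectin genes were lower adjusted over the list alone and 3 over all genes. Of the F-box, MATH and BATH genes, 7 were lower and 1 higher adjusted over the list alone, 5 and 1 over all genes. Of 3750 genes 466 passed, 312 higher and 154 lower in H4K5ac, and 76 of the higher ones were X-linked. Total count scaling gave 241 higher and 222 lower (52.1% higher against 67.0%). Equal IP strength, added after seeing the data, gave 200 higher and 248 lower. DESeq2 called 721, and a fit to the 6 IPs alone called 0, with 727 at an unadjusted p under 0.05. The count was 169 without H4K5ac IP replicate 1, 1095 without H4K5ac IP replicate 3, 116 without H4K8ac IP replicate 2 and 95 without H4K8ac IP replicate 3.

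**Figure D4:**
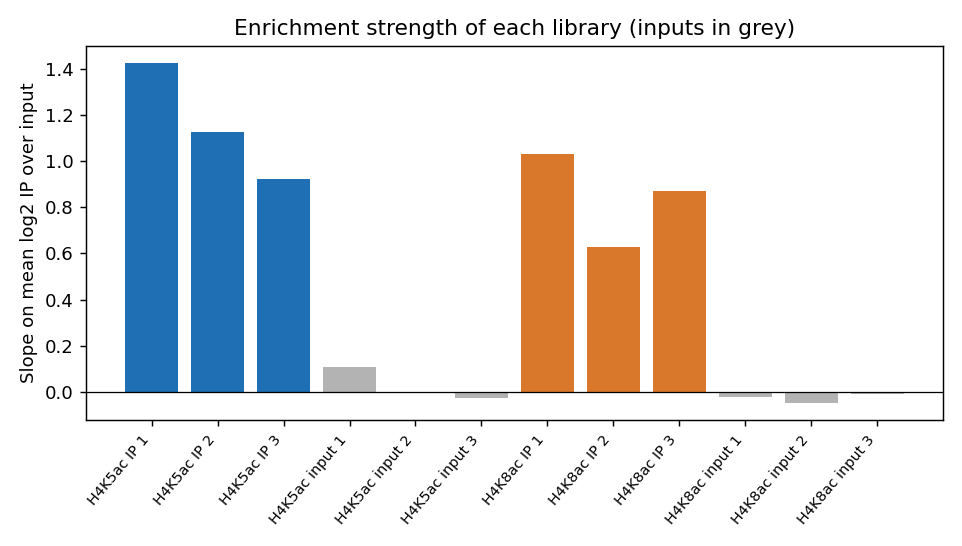
Slope of each library's log2 CPM, taken relative to the input mean, on the mean log2 IP over input of both marks, across 3750 genes (vertical axis, bars from 0). The H4K5ac IPs had slopes of 1.43, 1.13 and 0.92, the H4K8ac IPs 1.03, 0.63 and 0.87, and the inputs lay near 0.

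The libraries differed in how far the precipitate departed from input. The SD of log2 IP over input across genes was 0.38 ± 0.07 for H4K5ac and 0.30 ± 0.05 for H4K8ac (SD, n = 3), and the fold between the IPs correlated with the mean enrichment across genes (0.65). Among the 312 genes higher in the H4K5ac IPs, 65.4% lay in the highest of 4 equal classes of mean enrichment, against 2.60% of the 154 lower ones. The input DNA of the marks, compared as a negative control, gave 0 calls of 3750 in edgeR's quasi-likelihood test (180 at an unadjusted p under 0.05) and 0 with DESeq2. A single list, the nuclear hormone receptors, passed the preset test between the inputs (median -0.06, camera adjusted p = 0.0182, adjusted p = 0.454 with an estimated correlation). X-linked genes passed it too, unadjusted. Their H4K5ac input minus H4K8ac input median lay -0.025 from that of autosomal genes (camera p = 0.00588, p = 0.139 with an estimated correlation). A preset p of that size for X-linked genes therefore also arose without precipitation.

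X-linked genes were less enriched than autosomal genes for both marks. For H4K8ac the median of 575 X-linked genes lay -0.17 from that of 3175 autosomal genes, with 267 X-linked genes lower and 62 higher (camera p = 5.69e-11; p = 0.00481 with an estimated correlation). For H4K5ac the difference was -0.10, with 230 lower and 128 higher (camera p = 0.00376; p = 0.128 with an estimated correlation, and p = 0.0471 without H4K5ac IP replicate 2). It was negative in each of the 3 same-numbered pairs of IP and input, with a mean of -0.09 ± 0.03 for H4K5ac and -0.17 ± 0.03 for H4K8ac (SD, n = 3). The gap was wider for H4K8ac by 0.07 (camera p = 8.73e-07; p = 0.0192 with an estimated correlation), and 65.0% of X-linked but 45.4% of autosomal genes had the higher fold for H4K5ac. With an estimated correlation that difference did not pass without H4K8ac IP replicate 1 (0.074, p = 0.0985), with total count scaling (0.073, p = 0.138) or among genes above the median level (0.076, p = 0.0744), while its size stayed near the 0.074 of the main fit. Without the strongest and the weakest IP, a choice made after seeing the data, neither the difference (0.076, p = 0.0644) nor the H4K8ac gap (-0.16, p = 0.0951) passed with an estimated correlation. Among genes with no other gene within 2 kb, a choice made after seeing the data, the H4K5ac difference was -0.028 and no longer passed (camera p = 0.102 at the preset correlation).

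**Figure D5:**
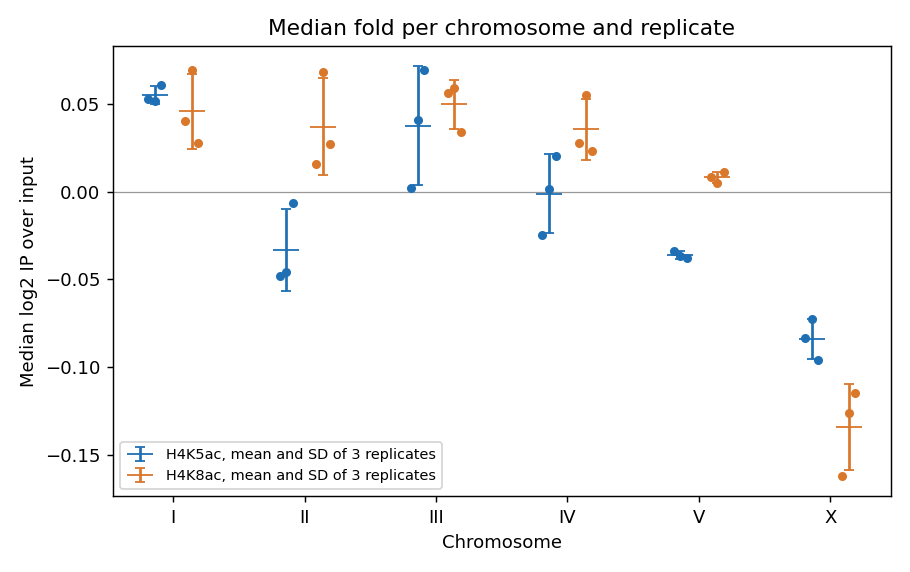
Median log2 IP over input of the genes of each chromosome (vertical axis), relative to the typical gene of both tables, for H4K5ac in blue and H4K8ac in orange; points are the 3 replicates, ticks and bars their mean and SD. The X chromosome lies lowest for both marks, further down for H4K8ac.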

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

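Chosen only after their results were seen were all tests of IP strength and of crowded genes, the X difference between the IPs, the spacing of the lectins, and the splits of the gene counts; the tests of the input sets for the 466 genes, and the splits for the X chromosome and the lectins were written down before their results were seen. A thinning of the lectins, also written down before, removed no gene and is replaced by their spacing. The X, lectin, ribosomal, chemoreceptor and F-box differences below were picked out because H4K5ac over input differed from H4K8ac over input by the test of the difference itself.

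The 466 genes called between the H4K5ac and H4K8ac IPs could come from the antibodies or from how strongly each library was enriched. They could also come from an error estimate shared by IPs and inputs. Replicate IPs mostly differed more (chi-square per degree of freedom 3.86 to 24.0) than replicate inputs (1.31 to 4.61), so that estimate may be too small for IPs. A fit to the IPs alone called 0 genes (727 at an unadjusted p under 0.05 in edgeR). That fit has fewer libraries to estimate the error from, so it cannot decide this, and the shared estimate stays open. With equal strength 59.7% of the calls stayed in the same direction, 158 of the 312 higher and 120 of the 154 lower. The offsets for equal strength were fitted to the same IPs and also removed spread between replicates. The error may then be too small and that share too high, and lower calls rose from 154 to 248. The share therefore argues only weakly against a straight-line effect of strength as the whole cause. An effect of another form was not removed, so strength as the whole cause stays open. As part of the cause it is in line with 559 calls when the 3 strongest IPs (H4K5ac replicates 1 and 2, H4K8ac replicate 1) were parted from the 3 weakest, a split that points to a structure of the samples. The input sets are argued against, since the signed input fold of the called genes was 0.123 of their IP fold. Of the 10 splits, 2 gave as many calls, the real one included, and 10 are too few for a share under 0.05. A difference between the marks stays open beside strength and the shared error estimate, as untested.

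X-linked genes were less low for H4K5ac than for H4K8ac by 0.07 on the log2 scale (camera p = 0.0192 with an estimated correlation, but 0.138 with total count scaling and 0.0744 among genes above the median level, where the difference stayed at 0.073 and 0.076). Reads divided with a gene lying within 2 kb of the TSS are argued against for this difference (0.081 ± 0.017, bootstrap SD, with no such gene). The same holds for the low H4K8ac value (-0.11 ± 0.03). For H4K5ac (-0.028 ± 0.038) crowding and a lower mark cannot be told apart, because the spread covers 0. Windows of genes with TSSs 2 to 4 kb apart can still overlap. Ratios of input replicates 2 and 3 correlated between neighbouring genes with TSSs 2 to 3 kb apart (0.30 for H4K5ac, 0.40 for H4K8ac). Reads divided at that distance were not removed, so they stay open. Equal IP strength left 0.11 ± 0.0069 (bootstrap SD over genes, which are not independent), which argues against a straight-line effect of strength. Over the 6 pairs of IP and input the X value rose with strength (Spearman correlation 0.66), so strength in another form stays open. The IP libraries alone differed by 0.048 ± 0.020 (SE, n = 3 per group). With 3 libraries per group this cannot decide whether the inputs were the whole cause. The fitted difference between the IPs was 0.060 (camera p = 0.0698 with an estimated correlation). Without H4K5ac IP replicate 2 it was 0.037 (camera p = 0.15 with an estimated correlation). Inputs as the whole or part of the cause stay open at -0.026 ± 0.016 between the input libraries. The fitted difference between the inputs was -0.025 (camera p = 0.00588 at the preset correlation, 0.139 with an estimated one), and -0.0087 without H4K5ac input replicate 1. The real value was the highest in 1 of 10 splits, with 0.0694 as the highest other against 0.0737, and 10 splits are too few for a share under 0.05, so a difference between the marks on the X may be offered only as a hypothesis.

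C-type lectin genes were lower for H4K5ac than for H4K8ac by a median of -0.20 (22 of 22 negative). Reads shared among these 22 are argued against if windows reach 2 kb, as inferred from the counts, since the closest pair lies 11.4 kb apart. Reads shared with other genes were not tested, as every such window holds at least 2 genes. Strength and mark cannot be told apart: the median stayed at -0.15 ± 0.01 (bootstrap SD) with equal IP strength, but the medians of the 6 pairs lay in the exact order of their strength (Spearman correlation -1.0). Of 10 splits, 2 gave as large a median, and the highest other, -0.22, again parted the 3 strongest pairs from the rest; 10 splits are too few for a share under 0.05. The adjusted p = 0.449 with an estimated correlation, and a difference between marks and a sample structure both stay open.

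Ribosomal protein genes differed between the marks by a median of 0.30 on the log2 scale, and by 0.11 with equal IP strength, where they no longer passed (camera adjusted p = 0.174). Chemoreceptor genes differed by -0.13, and by -0.096 with equal IP strength (camera adjusted p = 0.112). F-box, MATH and BATH genes differed by -0.11. With an estimated correlation none of these lists passed (adjusted p = 0.449 for ribosomal and 0.279 for chemoreceptor and F-box genes).

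Among the 10 splits of the libraries behind each remaining count, too few for a share under 0.05, the real H4K5ac split gave 2552 calls and the real H4K8ac split 2051, each in 1 of 10 splits with 0 as the highest other. For the difference between the marks over input and for the inputs, all 10 splits gave 0 calls in edgeR's quasi-likelihood test, like the real ones (549 and 180 genes at an unadjusted p under 0.05; 41 and 0 calls by DESeq2).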

How the results depend on the processing

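Alternatives named here as added were chosen after seeing the data. No X difference and none of the 10 list results past the preset test changed sign, relative to the median gene, under any alternative run. Named-gene results called in the main fit (158 of 166) did only under 1 scaling, given next. Sign changes of the uncalled ones were not counted. Lists that did not pass were less stable. In each mark's own table, fatty acid and triglyceride synthesis for H4K5ac had a median of -0.17 against 0.12. Insulin-like signalling and stress for H4K5ac had 0.19 against -0.0042, and lipolysis 0.27 against 0.11. For H4K8ac, lipolysis had 0.033 against -0.015 and lipid storage 0.024 against -0.019. Of 222 values of the comparisons under alternatives, 187 stayed on the same side of their threshold or within 1.5 times. For named genes 91 of 3010 values kept their sign but were no longer past the threshold, and 27 newly were. Another 30, all of results called in the main fit, changed sign. For lists 19 of 186 values were no longer past the threshold. Among added alternatives, genes with no other gene within 2 kb gave 530 calls for H4K5ac, 391 for H4K8ac, 46 between the IPs and 336 shared, fewer since only 805 genes were tested. There 0 lists passed for either mark or their difference. C-type lectins could not be tested there, as every lectin window holds at least 2 genes, and other lists may have lost members. The X difference for H4K5ac was -0.028 (camera p = 0.102 at the preset correlation). Each mark's own table gave 3676 H4K8ac calls among 5671 genes, and 8 lists for each mark. Equal IP strength gave 5 calls for the difference between the marks. Leaving out the strongest and the weakest IP gave 51 for that difference, 237 between the IPs, and 7 lists for H4K5ac; the cause was not tested.

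Scaling to the least enriched genes, an added alternative, raised all folds of a mark by its construction. Named genes called lower then changed sign in 17 cases for H4K5ac and 13 for H4K8ac. For H4K5ac they were R04E5.t6 0.023, Y105C5B.19 0.10, C09H10.17 0.0021, fasn-1 0.033, nhr-13 0.051, daf-2 0.12, cha-1 0.17, sbt-1 0.16 and tnt-2 0.084. The others were unc-15 0.051, lys-1 0.067, his-38 0.035, his-32 0.085, his-70 0.16, spe-48 0.16, clec-258 0.0072 and nhr-183 0.064. For H4K8ac they were Y16B4A.2 0.052, ftn-1 0.063, T14G11.6 0.090, fasn-1 0.059, daf-2 0.035, sbt-1 0.00057 and mec-7 0.097. The others were lys-1 0.12, his-38 0.072, msp-76 0.10, fbxc-52 0.091, clec-258 0.031 and Y92H12A.t1 0.011. List medians under that scaling and under total counts are set against the median gene, as in camera, and kept their sign.

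Among the alternatives fixed beforehand, leaving out 1 library gave 0 to 193 calls for the difference (193 without H4K5ac IP replicate 3), 95 to 1095 between the IPs, and 4 to 7 lists for H4K5ac. DESeq2 called 41 for the difference and 721 between the IPs, an adjusted p of 0.01 left 49 between the IPs, and a fit to the IPs alone 0 (727 at an unadjusted p under 0.05 in edgeR); the cause was not tested. With an estimated correlation 0 lists passed for either mark or their difference, also with the replicate block within mark, and the X difference for H4K5ac stayed -0.10 without passing (p = 0.128). The X difference between the marks, p = 0.0192 with an estimated correlation, then had p = 0.138 with total count scaling, 0.0744 among genes above the median level and 0.0985 without H4K8ac IP replicate 1, at differences of 0.073, 0.076 and 0.074 against 0.074. It had a difference of 0.076 and camera p = 0.0644 with an estimated correlation without the strongest and the weakest IP, an added alternative; the cause was not tested.

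With the replicate number as a block over all groups, H4K5ac had 2556 calls, H4K8ac 2083, the IPs 633, and the difference and the inputs 0 (619 and 212 at an unadjusted p under 0.05 in edgeR); within mark the first 2 were 2559 and 2079. Germline and oocyte genes then joined the lists that differ between marks (adjusted p = 0.0497 with the block, 0.0541 without; 0.369 in the main fit with an estimated correlation), and the block changed no other list's call. In H4K8ac, where the numbers do not pair, 1 of 6 libraries correlated best with its own number, against 4 of 6 in H4K5ac. The block within mark could not be fitted for the IPs or the inputs, the filter removed 0 genes and so tests nothing, and the alternatives for normalized units and for a stricter list of regions were not run. Overlap by 0.5 of the shorter region left 5598 of 5644 H4K5ac and 5262 of 5310 H4K8ac regions overlapping. In the simulation most differences between the marks of 0.32 on the log2 scale were missed (32.8% recovered); depth was not varied, so its share in this is not known.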

Other observations

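The fit of each mark's own table and the grouping of genes by region length and type were chosen after seeing the data, as were the genes named here, which lie outside the naming rule.

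Some genes listed for 1 mark only had high folds in that mark's own table. For H4K5ac the mitochondrial chaperone gene hsp-60 stood highest in its own table (log2 fold 1.94 ± 0.20, SE, n = 3 per group; edgeR adjusted p = 2.07e-05; promoter region at chromosome III 1612801 to 1625999). It was followed among genes outside the H4K8ac table by the proteasome gene rpn-3 (1.79 ± 0.14) and the chaperone gene hsp-90 (1.67 ± 0.14). The triglyceride lipase gene atgl-1 was higher (0.81 ± 0.09, edgeR adjusted p = 3.46e-05; promoter region at chromosome III 6415001 to 6424599), as was acdh-12, an acyl-CoA dehydrogenase gene (0.56 ± 0.08). Lower were the phospholipid synthesis gene pmt-2 (-0.37 ± 0.07), the lipid binding protein gene lbp-1 (-0.29 ± 0.07), the elongase gene elo-2 (-0.23 ± 0.08), acl-1 (-0.20 ± 0.07) and the desaturase gene fat-5 (-0.17 ± 0.07). The gene pod-2 did not pass (-0.16 ± 0.11, edgeR adjusted p = 0.236). For H4K8ac, Y22D7AL.10 (1.35 ± 0.11), whose region overlaps that given for hsp-60 with H4K5ac, the ribosomal protein gene rps-26 (1.26 ± 0.10) and maoc-1, a gene of peroxisomal fat oxidation (0.26 ± 0.07), were higher and pmp-4 lower (-0.26 ± 0.06). A gene listed for 1 mark only is not shown to differ between the marks, since the tables name 1 gene per region.

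In these own tables all 12 ribosomal and 8 of 9 proteasome genes were higher for H4K5ac (camera adjusted p = 3.09e-10 and 0.000108), and 9 of 10 and 6 of 7 for H4K8ac (3.46e-07 and 0.00066). Deacetylase complex genes were higher in 7 of 10 cases for H4K5ac, with 1 lower (camera adjusted p = 0.0406), and in 7 of 9 for H4K8ac (0.0078). Acetyltransferase and bromodomain genes were higher in 8 of 11 cases for H4K8ac, with 1 lower (camera adjusted p = 0.00422), and did not pass for H4K5ac (4 of 7 higher; 0.0615). The other lists past the preset test were low. For H4K5ac these were chemoreceptors (17 of 29 lower; camera adjusted p = 0.00642), F-box, MATH and BATH (24 of 57; 0.0406), C-type lectins (21 of 31; 0.001), nuclear hormone receptors (25 of 65; 0.00925) and piRNA genes (48 of 113; 0.0155). For H4K8ac they were chemoreceptors (28 of 42 lower; camera adjusted p = 0.00192), C-type lectins (22 of 52; 0.0209), nuclear hormone receptors (40 of 69; 0.000473) and piRNA genes (61 of 112; 0.00346). None of the 8 lists of either mark passed with an estimated correlation. The adjusted p was then 0.464 for all of H4K5ac and 0.31 to 0.805 for H4K8ac.

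Genes in longer H4K5ac regions had higher folds for both marks. Length was that of the first H4K5ac region listed for the gene, also where H4K8ac folds are given. Regions are called from IP enrichment, so their length is not independent of the fold. In 4 classes of H4K5ac region length, with median lengths of 1599, 3399, 5799 and 11799 bp, the median log2 fold for H4K5ac was -0.21 ± 0.05, -0.12 ± 0.03, 0.09 ± 0.01 and 0.30 ± 0.03 (SD, n = 3). For H4K8ac, in the same classes of H4K5ac region length, it was -0.14 ± 0.05, -0.09 ± 0.03, 0.09 ± 0.00 and 0.28 ± 0.05. Across genes, which are not independent replicates, H4K5ac region length had a Spearman correlation of 0.53 with the H4K5ac fold and 0.54 with the H4K8ac fold. By gene type, 23 microRNA genes had a median of 0.14 ± 0.04 for H4K5ac and 0.14 ± 0.06 for H4K8ac, and 548 short non-coding RNA genes -0.08 ± 0.05 and -0.04 ± 0.06.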
